A study of Mus musculus with 16 samples.

How the data were processed

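RNA from primary cortical astrocyte cultures of C57Bl/6 mice was measured on Illumina MouseRef-8 v2 BeadChips. Per the labels' protocols, microglia were removed with Ara-C and then L-leucine methyl ester. The 16 arrays form 4 groups of 4: basal, TGF-β1 (3 ng/ml) for 32 h, LPS (2 µg/ml) with IFNγ (3 ng/ml) for 8 h, and TGF-β1 for 24 h followed by 8 h with LPS plus IFNγ added. Per the labels, the time of TGF-β1 treatment was chosen from earlier nitric oxide experiments. The calcium recordings named by the series title are not analysed here. Replicates 1 and 2 of every group lie on slide 1, and replicates 3 and 4 on slide 2. Nothing in the labels says that the replicates are separate cultures, so the p-values measure only the spread between these samples, which may be technical.

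The authors extracted the signal with BeadStudio, per the submitters' processing notes (no version given), and deposited a table of intensity without scaling between arrays (85.6 to 44254.2). Whether background had been subtracted is not stated. It holds neither detection p-values nor control probes. The deposited series matrix holds log2 values; by calculation these are the logarithm of the same intensities after quantile normalization of the 16 arrays, without background subtraction (largest difference 5e-09). The intensity table was used, and the series matrix served as an alternative.

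Before the data were examined, background correction from negative controls, or from detection p-values, had been chosen. Since the table has neither, 1341 probes for olfactory, vomeronasal and taste receptors stood in as negative controls, a departure from that choice. A probe was above background on an array where fewer than 5% of these probes were as bright or brighter. Intensities were corrected by normexp with these probes (offset 16, robust), quantile normalized and taken to log2 with limma 3.58.1 in R 4.3.3 (the neqc procedure). Of 25697 probes 23978 carry 1 gene symbol, 0 several and 1719 none; 23962 symbols were matched by gene identifier and 0 changed. Probes above background on all 4 arrays of at least 1 group were kept, 12051 in all, and the probe brightest on average stood for each gene, which left 8843 genes, 2349 of them with several kept probes. Probes with no listed gene entered no comparison and are counted apart.

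The median intensity per array was 129.5 to 154.6, and the lowest correlation between arrays of a group was 0.979. Slide 1 had 13650 probes above background on average and slide 2 12920. The number of arrays limits the precision. The steps after normalization were tested on simulated data, in 10 sets with a slide difference like the measured one: of planted log2 changes 199 of 670 were found at 0.5, 533 of 670 at 1 and 656 of 660 at 2, and 28 of 1416 calls were false. Each set changed far fewer genes than the pairwise comparisons called, gave the genes independent noise and held no effect of LPS plus IFNγ. These rates thus need not hold for the measured comparisons.

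Each gene was fitted with limma (lmFit, contrasts.fit, eBayes), with 1 coefficient per group and all 16 arrays in the fit. The 6 comparisons are TGF-β1 against basal, LPS plus IFNγ against basal, both treatments against each of the other 3 groups, and the interaction. P-values of the moderated t-statistic were adjusted by Benjamini and Hochberg, and a gene passed at an adjusted p under 0.05. The 28 gene lists, covering inflammation, matrix, astrocyte function, receptor signalling, metabolism, stress, cell cycle and cell types, were tested with limma's camera at a preset correlation of 0.01 and adjusted over the lists within a comparison. Lists with fewer than 3 measured genes were not tested: of the sex-linked genes 2 were measured and 0 passed in any comparison. Where a gene lay above background on no array of a group, a lower bound for its fold was computed with that group set to the background limit.

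The replicate numbers in the labels are the only pairing. After removal of group means, arrays with the same number correlated at 0.25 to 0.67, arrays with another number on the same slide at 0.16 to 0.45, and arrays on different slides at -0.59 to -0.21. After removal of group and slide means, arrays with the same number correlated at 0.02 to 0.38. The numbers thus pair the arrays mostly through the slide. Results with the replicate number as a block are given beside the comparisons, and because the design is balanced the block leaves every log2 fold change as it is.

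Lists, comparisons, tests and the rule for naming genes were fixed before the data were examined. Named are, in each comparison, the 5 largest rises and 5 largest falls among genes past the threshold whose groups do not overlap, up to 4 members of each list with the smallest adjusted p, and fixed genes of nitric oxide, TGF-β, reactive astrocytes and receptors. Of these candidates, those whose call was lost under an alternative or without an array were mostly left out of the text after their values were seen. Of the fixed genes Smad7, C3, Adora2b, Adra2a, Grm5 and Ptafr have no probe under those names, and Tgfb1, Bdkrb2, Adra1b, C3ar1 and Ackr3 were not above background; they are not analysed here.

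Alternatives tried were the replicate number or slide as a block, each slide alone, no background subtraction, normexp with an offset of 50, median scaling, the series matrix values, no detection filter or a stricter one, each probe on its own, the mean of a gene's probes, moderation with trend and robust, only the compared groups in the fit, array weights, stricter thresholds and the removal of each array in turn. For the lists, camera with an estimated correlation, with a block, and fry were tried; camera with an estimated correlation and the slide block was added after the data were seen. Other splits of the arrays into groups were counted too, for the pairwise comparisons with the treatment effect left in the data.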

Results

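Astrocytes, the glial cells that enwrap synapses and clear transmitters, were cultured from mouse cortex and exposed to TGF-β1, to lipopolysaccharide (LPS) with interferon-γ (IFNγ), or to both in turn. The series asks how such inflammatory mediators alter astrocyte gene expression and the calcium signals evoked through G-protein-coupled receptors. The calcium recordings are not analysed here. The 4 groups held 4 arrays each: basal cultures, TGF-β1 for 32 h, LPS plus IFNγ for the last 8 h, and TGF-β1 for 24 h followed by 8 h with LPS plus IFNγ added. Median raw intensity per array ran from 129.5 to 154.6, and 12649 to 14182 of 25697 probes (49.2 to 55.2%) lay above background. With 4 arrays per group, the number of arrays limits the precision: in simulated arrays with the measured spread and slide difference, 533 of 670 planted log2 changes of 1 and 199 of 670 of 0.5 were called. The simulated sets changed far fewer genes, with independent noise, so the rates in the measured comparisons may differ. Every group had 2 arrays on each of 2 slides. LPS plus IFNγ parted the arrays on the first principal component (71.6% of variance), TGF-β1 on the second (9.9%) and the slide on the third (7.25%).

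**Figure D1:**
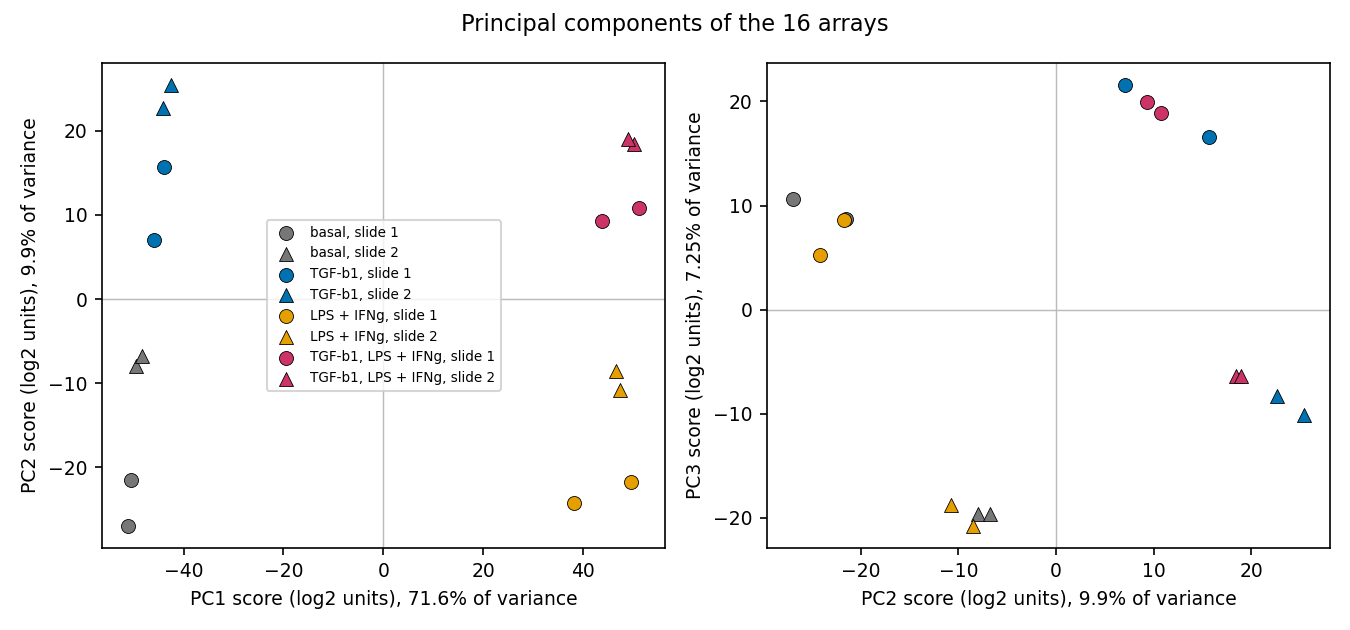
Scores of the 16 arrays on the first 3 principal components of log2 intensity, in log2 units (colours, groups; circles, slide 1; triangles, slide 2). The 8 arrays with LPS plus IFNγ lie right of 0 on the first component, the 8 with TGF-β1 above 0 on the second, and slide 1 above 0 on the third.

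With TGF-β1 alone, lists of extracellular matrix, contractile and cholesterol synthesis genes lay higher and cell-cycle genes lower. All 4 list calls were lost with an estimated correlation (adjusted p = 0.183 each). Mfap4, which codes for a microfibril protein of the extracellular matrix, rose the most, by 4.54 ± 0.18 on the log2 scale (estimate ± standard error, 4 arrays per group). Pmepa1, a SMAD target that limits TGF-β signalling, rose by 2.71 ± 0.14. Nos2, the gene of inducible nitric oxide synthase, did not pass the threshold (-0.10 ± 0.29). It lay above background on 1 of 4 basal and on 0 of 4 TGF-β1 arrays, so an effect cannot be measured there. This comparison asks what 32 h of the cytokine does to astrocytes that meet no inflammatory signal.

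Of 8843 genes tested, 562 were higher and 557 lower than in basal cultures, 247 of them by at least 1 on the log2 scale. With the replicate number as a block 2086 genes passed (929 higher, 1157 lower), among them all 1119, and with the slide as a block 1983. Within slide 1 alone 541 passed, and within slide 2 alone 726. After Mfap4, the next rises were those of Ripply1 (3.56 ± 0.24), a transcriptional corepressor, of the stress protein gene Nupr1 (3.29 ± 0.39), of Eps8l2 (3.05 ± 0.23, above background on 1 of 4 basal arrays) and of the small GTPase gene Rasl11b (2.80 ± 0.23). Sertm1 (-2.44 ± 0.19), the orphan receptor gene Gpr12 (-1.95 ± 0.17, above background on 2 of 4 TGF-β1 arrays), the TNF receptor adaptor gene Traf1 (-1.84 ± 0.28) and the β-defensin gene Defb10 (-1.83 ± 0.27, 3 of 4 TGF-β1 arrays) were among the largest falls.

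Among 32 measured genes of the extracellular matrix, 10 rose and 1 fell (13 and 1 adjusted over the list alone), with a median log2 fold change of 0.23 (0.24 and 0.22 within the slides). The list stood apart from the other genes by camera (adjusted p = 3.4e-05, and adjusted p = 0.183 with an estimated correlation). The cross-linking enzyme genes Lox (2.69 ± 0.22, 3 of 4 basal arrays above background) and Loxl1 (2.17 ± 0.17), the proteoglycan gene Bgn (1.83 ± 0.21) and the collagen hydroxylase gene Plod2 (1.52 ± 0.14) rose. Of 22 contractile and actin genes, 6 rose and 0 fell by limma (8 and 1 adjusted over the list alone). Pdlim7 (1.48 ± 0.16), Tagln (1.07 ± 0.14) and Zyx (0.50 ± 0.08) were among them. Their median was 0.33 (0.40 and 0.14 within the slides, adjusted p = 0.00011, and adjusted p = 0.183 with an estimated correlation). Of 10 markers of fibroblasts, pericytes and meninges 1 rose and 2 fell. The median was -0.18 (camera adjusted p = 0.63), while fry called the list lower (0.00453), and Dcn, a matrix proteoglycan gene, was at least 1.25-fold lower. Matrix proteases and their inhibitors had 4 of 18 members higher and 1 lower (6 and 1 adjusted over the list alone), with Adam12 (1.73 ± 0.19), Timp1 (1.68 ± 0.15) and Timp4 (1.21 ± 0.21) higher and Timp2 (-0.50 ± 0.10) lower. The list did not pass camera (adjusted p = 0.0855), while fry called it higher (0.00107).

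Cholesterol synthesis had the highest median of the lists that passed. Of its 20 measured genes 12 rose (15 adjusted over the list alone), among them Cyp51 (1.34 ± 0.25), Mvd (1.08 ± 0.19), Idi1 (0.89 ± 0.18) and Ebp (0.57 ± 0.10), and the median was 0.63 (0.73 and 0.47 within the slides, adjusted p = 5.8e-10, and adjusted p = 0.183 with an estimated correlation). Cell-cycle genes went the other way: 14 of 27 fell (18 adjusted over the list alone), with Cdc20 (-1.24 ± 0.24, 1 of its 4 probes not past), Cdk1 (-1.04 ± 0.19), Nusap1 (-0.91 ± 0.19) and Mcm4 (-0.64 ± 0.14), and the median was -0.70 (-0.63 and -0.74 within the slides, -0.38 without background subtraction, adjusted p = 9.7e-08, and adjusted p = 0.183 with an estimated correlation). Ependymal markers had a median of -0.66 in the same arrays, with 1 of 8 lower (adjusted p = 0.0418, and adjusted p = 0.414 with an estimated correlation). Stress and unfolded protein response genes had 5 of 23 members higher and 2 lower, with Hspb1 (2.45 ± 0.39), Gadd45a (1.41 ± 0.22), Xbp1 (0.69 ± 0.12) and Atf4 (0.62 ± 0.13) higher (adjusted p = 0.0118, and adjusted p = 0.486 with an estimated correlation).

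In the TGF-β and SMAD list 5 of 35 genes rose and 7 fell, and its median (-0.09) and mean (0.08) differ in sign (adjusted p = 0.856). The BMP-responsive gene Id1 (-0.58 ± 0.09) and the ligand gene Tgfb2 (-0.67 ± 0.12) were lower. Of 41 interferon-response genes 12 fell and 0 rose (15 and 1 adjusted over the list alone), among them Gbp3 (-1.06 ± 0.14), Igtp (-0.62 ± 0.09) and Usp18 (-0.51 ± 0.10, 1 of its 3 probes not past). The median was -0.12 (-0.06 without background subtraction, adjusted p = 0.0042, and adjusted p = 0.206 with an estimated correlation). The chemokine gene Cxcl10 rose by 0.97 ± 0.22, with 3 of 27 cytokines and chemokines higher and 1 lower (adjusted p = 0.53). In antigen presentation 3 of 26 genes were higher, such as H2-DMa (0.96 ± 0.21), and 2 lower, such as H2-T23 (-0.62 ± 0.10). Of 32 genes of NF-κB and Toll-like receptor signalling, 2 were higher, with Irak2 at 1.09 ± 0.15, and 1 was lower.

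Of 31 astrocyte markers 2 rose and 5 fell (2 and 9 adjusted over the list alone). The median was -0.32 (-0.28 and -0.30 within the slides, adjusted p = 0.0335, and adjusted p = 0.757 with an estimated correlation). The urea transporter gene Slc14a1 rose (0.95 ± 0.15, 1 of its 2 probes not past) and Cbs fell (-0.86 ± 0.17). The glutamate transporter gene Slc1a3 (-0.02 ± 0.11) did not pass. Gfap (-0.27 ± 0.36) passed only with the replicate block (adjusted p = 0.0307) and Slc1a2 (-0.50 ± 0.29) only with a block (0.00514 with the replicate number, 0.00306 with the slide). Among reactive astrocyte genes 7 of 29 rose, including Ptx3 (0.97 ± 0.17), and 2 fell (adjusted p = 0.317). Markers of other cells moved both ways: the neuronal growth gene Gap43 rose (1.58 ± 0.27) and Reln fell (-1.47 ± 0.20), 4 and 1 of 11 neuron markers, and 2 of 7 oligodendrocyte-lineage markers rose and 2 fell, Pdgfra among the latter (-1.10 ± 0.25, 1 of 4 TGF-β1 arrays above background). Of 7 microglia markers 0 passed by limma (0 before adjustment), and neither camera (adjusted p = 0.856) nor fry (0.843) called the list.

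**Figure D2:**
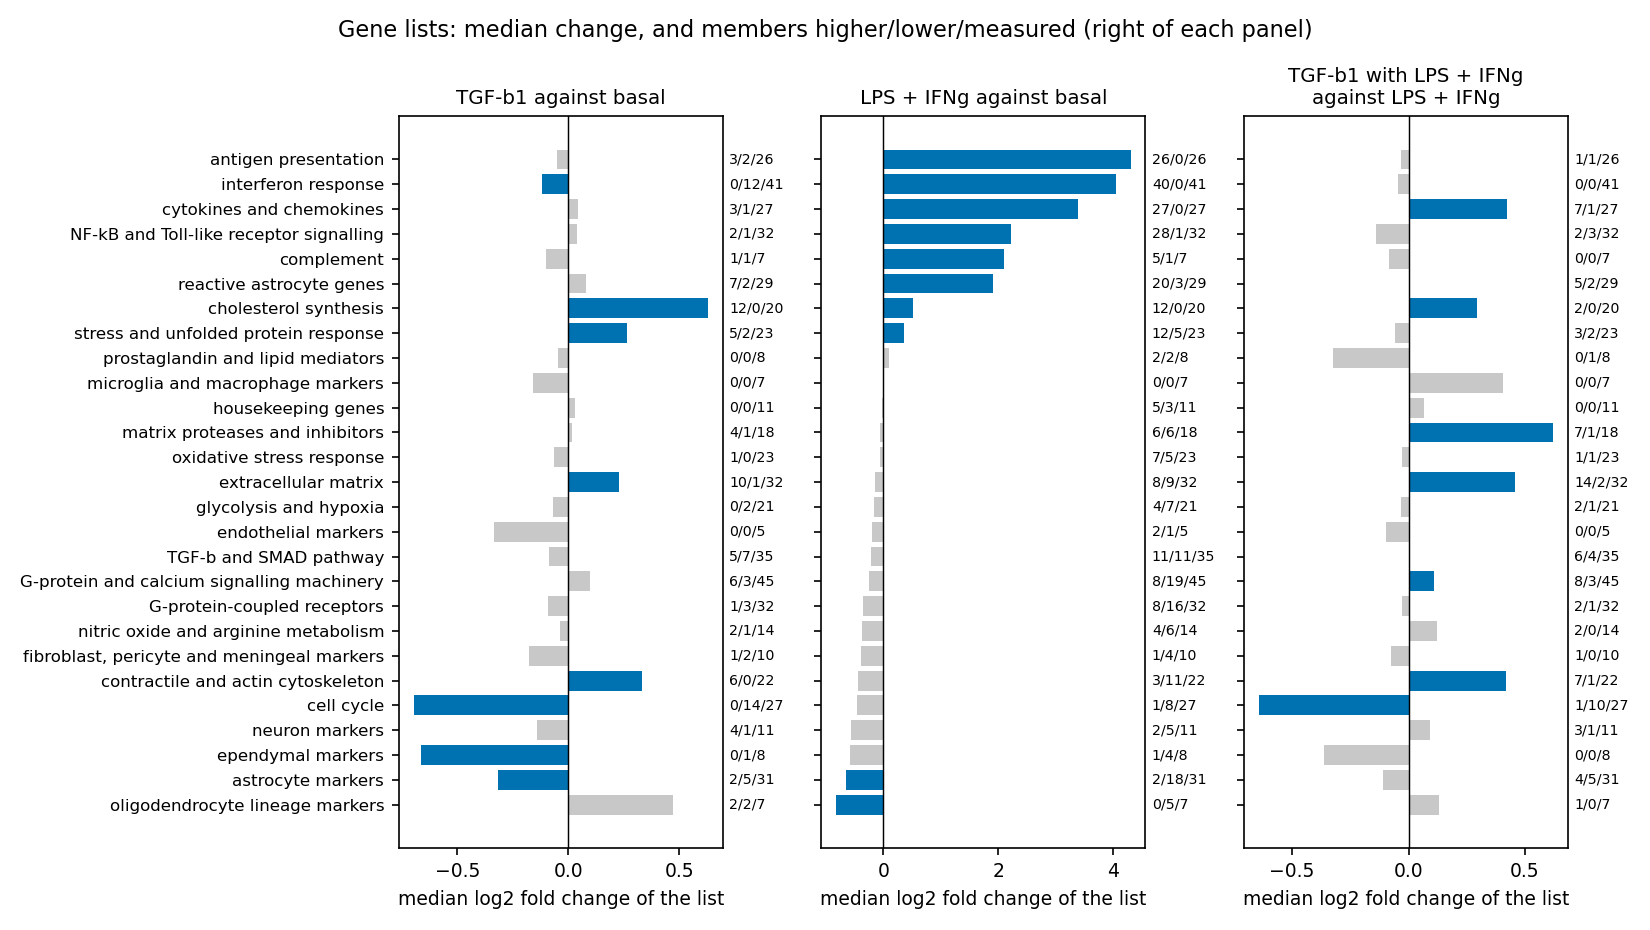
Bars give the median log2 fold change of each gene list in 3 comparisons, blue where camera's adjusted p lay under 0.05, with the members higher, lower and measured at the right. LPS plus IFNγ raised 26 of 26 antigen presentation genes and 40 of 41 interferon-response genes, and TGF-β1 raised 12 of 20 cholesterol genes.

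LPS plus IFNγ changed 4586 genes against 1119 with TGF-β1, or 5462 against 2086 with the replicate block. Cxcl9, a chemokine that draws T cells, rose at least 787-fold (log2 fold change 10.17 ± 0.16, 4 arrays per group); it lay above background on no basal array. Nos2 rose by 2.89 ± 0.29 on the log2 scale (above background on 1 of 4 basal arrays). Gja1, the gap junction protein that couples astrocytes, fell (-1.12 ± 0.15), as did the purine receptor gene P2ry1 (-1.64 ± 0.15) and the endothelin receptor gene Ednrb (-1.34 ± 0.13). This comparison asks what 8 h of a bacterial and a T-cell signal do to astrocytes.

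By limma 1792 genes were higher and 2794 lower, 1583 of them by at least 1 on the log2 scale, and the median log2 fold change of all genes was -0.12. With the slide as a block 5388 passed. Other leading rises were those of the chemokine genes Cxcl1 (9.71 ± 0.37, 1 of 4 basal arrays above background), Ccl5 (9.33 ± 0.18, 3 of 4) and Ccl7 (9.02 ± 0.26, 1 of 4) and of the interferon-induced GTPase gene Ifi47 (8.62 ± 0.17, 1 of 4). Fam107a (-3.68 ± 0.26), Lmcd1 (-3.43 ± 0.25, above background on 1 of 4 LPS plus IFNγ arrays, and up to -1.42 over its 3 probes), Sertm1 (-3.40 ± 0.19), Aif1l (-3.37 ± 0.40) and Ppp1r1b (-3.34 ± 0.44, or -1.27 as the mean of its detected probes, 2 of its 3 probes not past) fell the most. A fold given as at least sets the mean of the treated arrays against the background limit of the basal arrays.

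All 27 measured cytokines and chemokines rose. The median was 3.40 (3.15 with genes absent from basal arrays at their bound, and 1.84 without background subtraction; adjusted p = 3.2e-20). Cxcl10 rose by 8.57 ± 0.22, Ccl2 at least 277-fold and Il6 by at least 3.46 on the log2 scale. Of 41 interferon-response genes 40 rose, with Isg15 at 6.65 ± 0.11, Usp18 at 6.02 ± 0.10, Igtp at 5.21 ± 0.09 and the transcription factor gene Irf1 at 4.05 ± 0.12 (median 4.05, or 3.95 at the bounds; adjusted p = 3.5e-39). Antigen presentation had 26 of 26 genes higher (median 4.31, adjusted p = 1.7e-27): the checkpoint ligand gene Cd274 (6.55 ± 0.14), H2-T23 (5.36 ± 0.10), the invariant chain gene Cd74 (at least 122-fold) and its regulator Ciita (at least 24.2-fold). In NF-κB and Toll-like receptor signalling 28 of 32 rose and 1 fell (median 2.22, or 1.38 without background subtraction; adjusted p = 2e-19), with Tlr2 (7.52 ± 0.16), the inhibitor gene Nfkbia (3.94 ± 0.14) and the adaptor gene Myd88 (3.09 ± 0.10). Complement had 5 of 7 members higher and 1 lower (median 2.11, adjusted p = 0.00131), among them C1s1 (4.33 ± 0.19), C2 (at least 18.9-fold), Cfb (by at least 3.46) and Serping1 (2.11 ± 0.12). Reactive astrocyte genes had 20 of 29 higher and 3 lower (median 1.91, or 1.13 without background subtraction; adjusted p = 4.7e-11), with Ptx3 (7.90 ± 0.17) and the lipocalin gene Lcn2 (5.14 ± 0.27). These 6 lists kept their call with an estimated correlation, at adjusted p from 8.7e-07 to 0.0139. Within the slides their medians ran from 1.81 to 4.51.

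Of 7 measured microglia markers 0 rose and 0 fell by limma beside these rises (0 before adjustment). Fitted on each slide alone, 2 passed on slide 1 and 3 on slide 2. Neither camera (adjusted p = 0.991) nor fry (0.717) called the list, whose median was -0.01 (-0.69 within slide 1 and 0.69 within slide 2). Only 7 of 23 such markers on the array lay above background. Markers of other cells did move: 5 of 7 oligodendrocyte-lineage genes fell, with Lims2 at -2.63 ± 0.15, Olig1 at -1.27 ± 0.20 and Cnp at -0.97 ± 0.13 (median -0.82, or -0.70 at the bounds, -0.39 with an offset of 50 and -0.26 without background subtraction; adjusted p = 0.0471, and adjusted p = 0.118 with an estimated correlation, 0.0508 with the replicate block). Neuron markers had 2 of 11 higher and 5 lower, with Gap43 at 2.81 ± 0.27 and Map2 at -1.30 ± 0.16. Of 5 endothelial markers 2 rose, Flt1 (1.92 ± 0.24, 3 of 4 basal arrays) and Ly6c1 (3.41 ± 0.16, 1 of 4), and 1 fell. Fibroblast and meningeal markers had 1 of 10 higher, Apod (at least 4.16-fold), and 4 lower, with Thy1 at -1.02 ± 0.20. Ependymal markers had 1 of 8 higher, Rarres2 (2.45-fold), and 4 lower, with Tekt1 at -1.96 ± 0.45.

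Of 31 astrocyte markers 18 fell and 2 rose. The median was -0.65 (-0.65 and -0.66 within the slides, adjusted p = 0.012, and adjusted p = 0.653 with an estimated correlation). The zinc transporter gene Slc39a12 (-1.70 ± 0.13), the growth factor receptor gene Fgfr3 (-1.69 ± 0.23) and Cbs (-1.23 ± 0.17) were lower, as was Gja1. The glutamate transporter gene Slc1a2 was higher (0.71, and 0.71 to 0.89 over its 3 probes, 1 of them not past). The connexin gene Gjb2 was also higher, by less than its 4.56 with both treatments. Slc1a3 did not pass (-0.06 ± 0.11). Gfap, the intermediate filament gene that marks astrocytes, passed with a block (-0.64 ± 0.36; adjusted p = 1.7e-05 with the replicate number and 0.000158 with the slide) and not without one (adjusted p = 0.145). Vim, another intermediate filament gene, fell (-0.50 ± 0.15), but not with median scaling (-0.29, adjusted p = 0.15). Beside the astrocyte markers, contractile genes had 11 of 22 members lower and 3 higher (adjusted p = 0.157), with Lmod1 (-1.74 ± 0.21, 2 of 4 LPS plus IFNγ arrays above background) and Tpm1 (-0.86 ± 0.10) lower and Csrp1 (0.71 ± 0.09) higher.

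Metabolic and matrix genes divided. Cholesterol synthesis had 12 of 20 members higher (13 adjusted over the list alone), Fdps (1.74 ± 0.26), Cyp51 (1.62 ± 0.25), Lss (1.60 ± 0.22) and Mvd (1.41 ± 0.19) among them (median 0.52, adjusted p = 0.000823, and adjusted p = 0.493 with an estimated correlation). Stress genes had 12 of 23 higher and 5 lower, with Atf3 (3.59 ± 0.16), Gadd45b (2.31 ± 0.15), Atf4 (1.80 ± 0.13) and Creld2 (1.64 ± 0.15) higher (median 0.35, adjusted p = 0.00808, and adjusted p = 0.493 with an estimated correlation). Of 27 cell-cycle genes 8 fell, with Cdt1 (-2.18 ± 0.31) and Mcm4 (-1.51 ± 0.14), and 1 rose, the spindle gene Tpx2 (1.83 ± 0.19; adjusted p = 0.157 for the list). Extracellular matrix had 8 of 32 higher and 9 lower, with a median of -0.14 (-0.02 and -0.28 within the slides) and a mean of 0.10; the hyaluronan synthase gene Has2 rose at least 5.28-fold, Col4a1 by 1.86 ± 0.23 and Thbs2 by 1.32 ± 0.14, and Fmod fell (-1.27 ± 0.12; adjusted p = 0.617). Among 18 proteases and inhibitors 6 rose, such as Timp1 (3.94 ± 0.15) and Mmp3 (4.02 ± 0.43, 1 of 4 basal arrays), and 6 fell, such as Timp4 (-2.07 ± 0.21) and Timp3 (-1.36 ± 0.15; adjusted p = 0.641). The TGF-β and SMAD list had 11 of 35 higher and 11 lower, with a median of -0.21 (-0.11 and -0.12 within the slides, -0.07 without background subtraction) and a mean of 0.15: Junb (2.93 ± 0.18), Smad3 (1.74 ± 0.16), Cdkn2b (1.73 ± 0.16) and the receptor gene Tgfbr2 (0.77 ± 0.20) rose, and Ccn2 fell (-0.94 ± 0.09).

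Nitric oxide and lipid mediator genes went both ways. Gch1, whose enzyme makes the synthase cofactor tetrahydrobiopterin, rose by 5.12 ± 0.16, and the arginine-recycling gene Ass1 (-1.52 ± 0.13) and the nitric oxide receptor gene Gucy1a1 (-1.30 ± 0.26, 3 of 4 LPS plus IFNγ arrays) fell. In that list of 14 genes 4 rose and 6 fell, with a median of -0.36 and a mean of 0.20; camera did not call it (adjusted p = 0.991) and fry called it higher (adjusted p = 0.000553). The prostaglandin synthase genes Ptges (3.45 ± 0.13) and Ptges2 (2.27 ± 0.16) rose, 2 of 8 in their list, and 2 fell. Oxidative stress genes had 7 of 23 higher, with Sod2 at 1.59 ± 0.12 and the cystine transporter gene Slc7a11 at 4.72 ± 0.39 (2 of 4 basal arrays), and 5 lower. Glycolysis and hypoxia had 4 of 21 higher, with Hk2 at 2.07 ± 0.19, and 7 lower, with Pfkp at -1.55 ± 0.14. Of 11 commonly used reference genes 5 rose, B2m by 1.01 ± 0.10, and 3 fell, with Gusb at -0.84 ± 0.09 (1 of its 3 probes not past).

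Added after TGF-β1, LPS plus IFNγ still raised the inflammatory genes, and TGF-β1 left its own mark on the matrix and on a few cytokines. Il11, a cytokine of the IL-6 family, was 4.61 ± 0.20 higher on the log2 scale than with LPS plus IFNγ alone (4 arrays per group), Il6 2.10 ± 0.29 higher and Nos2 1.64 ± 0.29 higher. Cxcl10 (-0.05 ± 0.22), Ccl2 (0.26 ± 0.18), Irf1 (-0.13 ± 0.12) and Lcn2 (0.00 ± 0.27) did not pass. Their means lie over 13 on the log2 scale in both groups, near its top of 15.23, where a further rise may not show. This comparison, TGF-β1 then LPS plus IFNγ against LPS plus IFNγ, asks whether TGF-β1 alters the inflammatory response.

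By limma 502 genes were higher and 358 lower, 231 of them by at least 1 on the log2 scale. With the replicate block 1594 passed, 753 higher and 841 lower, among them all 860, and with the slide block 1474; the share of rises went from 58.4% to 47.2% and 48.3%. Within slide 1 505 passed and within slide 2 609. Mfap4 (4.28 ± 0.18), Lox (4.02 ± 0.22, 3 of 4 LPS plus IFNγ arrays above background), the matricellular gene Ccn4 (3.50 ± 0.22, or 2.16 as the mean of its detected probes) and Rasl11b (3.50 ± 0.23) followed Il11. Nat8 (-1.82 ± 0.41, 3 of 4 arrays with TGF-β1 and LPS plus IFNγ), the ligand gene Wnt7a (-1.75 ± 0.22), Rcsd1 (-1.57 ± 0.16) and Osgin1 (-1.53 ± 0.16) were among the largest falls.

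Of 32 matrix genes 14 were higher and 2 lower (17 and 3 adjusted over the list alone), with Eln (3.33 ± 0.36, 3 of 4 LPS plus IFNγ arrays above background), Plod2 (1.77 ± 0.14) and Tnc (1.37 ± 0.13) beside Lox. The median was 0.46 (0.51 and 0.48 within the slides, adjusted p = 4.5e-09, and 0.0253 with an estimated correlation, but 0.0831 with the slide block added, a setting chosen after seeing the data). Proteases and inhibitors had 7 of 18 higher and 1 lower, with Timp4 (1.45 ± 0.21), Adam12 (1.38 ± 0.19), Timp1 (0.88 ± 0.15) and Timp3 (0.87 ± 0.15) higher (median 0.62, 0.69 and 0.37 within the slides, 0.22 without background subtraction, adjusted p = 0.000236, and 0.0225 with an estimated correlation, but 0.0831 with the slide block added). Contractile genes had 7 of 22 higher and 1 lower (12 and 1 adjusted over the list alone), with the fibronectin receptor gene Itga5 (1.73 ± 0.17), Pdlim7 (1.41 ± 0.16), Tagln (1.14 ± 0.14) and Zyx (0.47 ± 0.08) higher (median 0.42, 0.45 and 0.25 within the slides, 0.26 without background subtraction, adjusted p = 1.1e-05, and 0.0428 with an estimated correlation, but 0.167 with the slide block added). Fibroblast and meningeal markers had 1 of 10 higher and a median of -0.08 beside these lists. In the TGF-β and SMAD list 6 of 35 rose, with Pmepa1 (2.45 ± 0.14) and Ccn2 (0.95 ± 0.09), and 4 fell, with Id1 (-0.54 ± 0.09) and Id3 (-0.88 ± 0.13; adjusted p = 0.279).

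Among 27 cytokines and chemokines 7 were higher and 1 lower (8 and 1 adjusted over the list alone): the leukaemia inhibitory factor gene Lif (2.32 ± 0.22), Il6, Tnfsf13b (1.33 ± 0.18) and Ccl8 (0.85 ± 0.15) rose, and the median was 0.42 (0.34 and 0.44 within the slides, adjusted p = 0.000168, and adjusted p = 0.204 with an estimated correlation). Of 41 interferon-response genes, 16 of them over 13 in both groups, 0 passed in either direction by limma (7 before adjustment, 0 adjusted over the list alone; camera adjusted p = 0.562, fry 0.293), and the median was -0.05. In antigen presentation 1 of 26 was higher, Ciita (0.52 ± 0.11), and 1 lower. NF-κB and Toll-like receptor signalling had 2 of 32 higher, with Irak2 at 0.92 ± 0.15, and 3 lower (adjusted p = 0.21). In the nitric oxide list Nos2 and Ass1 (0.81 ± 0.13) rose, 2 of 14. Microglia markers had 0 of 7 past the limma test (1 before adjustment) and a median of 0.41 (0.18 without background subtraction; camera adjusted p = 0.384, fry 0.589).

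Cell-cycle genes were lower again, 10 of 27, with 1 higher (18 and 1 adjusted over the list alone): Kif2c (-1.30 ± 0.24, 2 of 4 arrays with TGF-β1 and LPS plus IFNγ above background), Cdk1 (-1.21 ± 0.19) and Nusap1 (-1.09 ± 0.19) fell and Mcm6 (1.35 ± 0.12) rose. The median was -0.64 (-0.61 and -0.63 within the slides, -0.37 without background subtraction, adjusted p = 9.3e-07, and adjusted p = 0.2 with an estimated correlation); ependymal markers had a median of -0.36 in these arrays, with 0 of 8 past the limma test (0 before adjustment; camera adjusted p = 0.279, fry 0.144). Cholesterol synthesis had 2 of 20 members higher (median 0.29, 0.36 and 0.15 within the slides, adjusted p = 0.000414, and adjusted p = 0.498 with an estimated correlation). Astrocyte markers had 4 of 31 higher and 5 lower (adjusted p = 0.633): the connexin gene Gjb2 (1.96 ± 0.42) and the glycine transporter gene Slc6a9 (0.74 ± 0.13) rose, and the progenitor marker Fabp7 fell (-1.14 ± 0.20). Gfap did not pass (-0.11 ± 0.36). Among reactive astrocyte genes 5 of 29 rose, with Hspb1 (2.55 ± 0.39) and the sphingosine kinase gene Sphk1 (2.52 ± 0.38), and 2 fell. Gadd45a (1.75 ± 0.22) rose and the stress factor genes Ddit3 (-0.86 ± 0.18) and Atf3 (-0.67 ± 0.16) fell, in a list with 3 of 23 higher and 2 lower. The NADPH oxidase gene Nox4 rose by 1.73 ± 0.31.

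Receptor-evoked calcium signalling is named by the series title. Of 32 measured G-protein-coupled receptors 8 rose and 16 fell with LPS plus IFNγ (10 and 17 adjusted over the list alone; median -0.35, or -0.26 at the bounds, -0.23 without background subtraction, and -0.27 and -0.37 within the slides). Camera did not call the list (adjusted p = 0.611) and fry called it lower (adjusted p = 5.6e-05), as 1 of 23 among 27 lists that fry called in this comparison. Beside P2ry1 and Ednrb, the galanin receptor gene Galr2 fell at least 1.66-fold, while the sphingosine 1-phosphate receptor gene S1pr3 (2.10 ± 0.20) and the UDP-glucose receptor gene P2ry14 (at least 1.33-fold) rose. TGF-β1 alone left 1 receptor higher and 3 lower, with Ednrb at -0.58 ± 0.13 (adjusted p = 0.0897 as the mean of its detected probes); the thrombin receptor gene F2r (0.13 ± 0.11) and S1pr3 (-0.14 ± 0.20) did not pass. Added before LPS plus IFNγ, TGF-β1 gave 2 higher, the UDP receptor gene P2ry6 (1.92 ± 0.26) and P2ry14 (1.09 ± 0.21), and 1 lower. Ednrb (-0.35 ± 0.13) and F2r (0.27 ± 0.11) passed there only with a block (adjusted p = 0.00708 and 0.0425 with the replicate number), and P2ry1 (0.19 ± 0.15) and S1pr3 (0.00 ± 0.20) did not pass.

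In the 45 genes of G-protein and calcium signalling machinery, LPS plus IFNγ raised 8 and lowered 19 (median -0.24, and -0.10 and -0.27 within the slides; camera adjusted p = 0.611, fry adjusted p = 0.000145). The store calcium sensor gene Stim1 (-1.59 ± 0.12), Rgs3 (-1.13 ± 0.15, and -1.88 to -0.11 over its 4 probes, 2 of them not past) and Rgs2 (at least 1.77-fold lower) fell. The G-protein signalling regulators Rgs16 (2.94 ± 0.21) and Rgs4 (1.45 ± 0.31) and the IP3 receptor gene Itpr2 (0.58 ± 0.14) rose. TGF-β1 alone raised 6 and lowered 3, with the phospholipase C genes Plce1 (0.67 ± 0.15) higher and Plcd4 (-0.68 ± 0.15, 2 of its 3 probes not past) and Rgs4 (-1.21 ± 0.31, adjusted p = 0.0168) lower. Itpr2 did not pass (0.20 ± 0.14). The Rgs4 call was lost with only the compared groups in the fit (adjusted p = 0.0507) and without basal replicate 1 (0.0527) or 2 (0.059) or TGF-β1 replicate 4 (0.0552). With LPS plus IFNγ, TGF-β1 raised 8 and lowered 3 (13 and 4 adjusted over the list alone): Rgs17 (1.09 ± 0.20) and the scaffold gene Homer1 (0.59 ± 0.10) rose and Rgs4 (-1.49 ± 0.31) and Plcd4 (-0.75 ± 0.15, 2 of its 3 probes not past) fell, with Itpr2 not past (0.05 ± 0.14). That list passed camera (median 0.11, 0.17 and 0.16 within the slides, 0.05 without background subtraction, adjusted p = 0.0103, and adjusted p = 0.0787 with an estimated correlation).

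**Figure D3:**
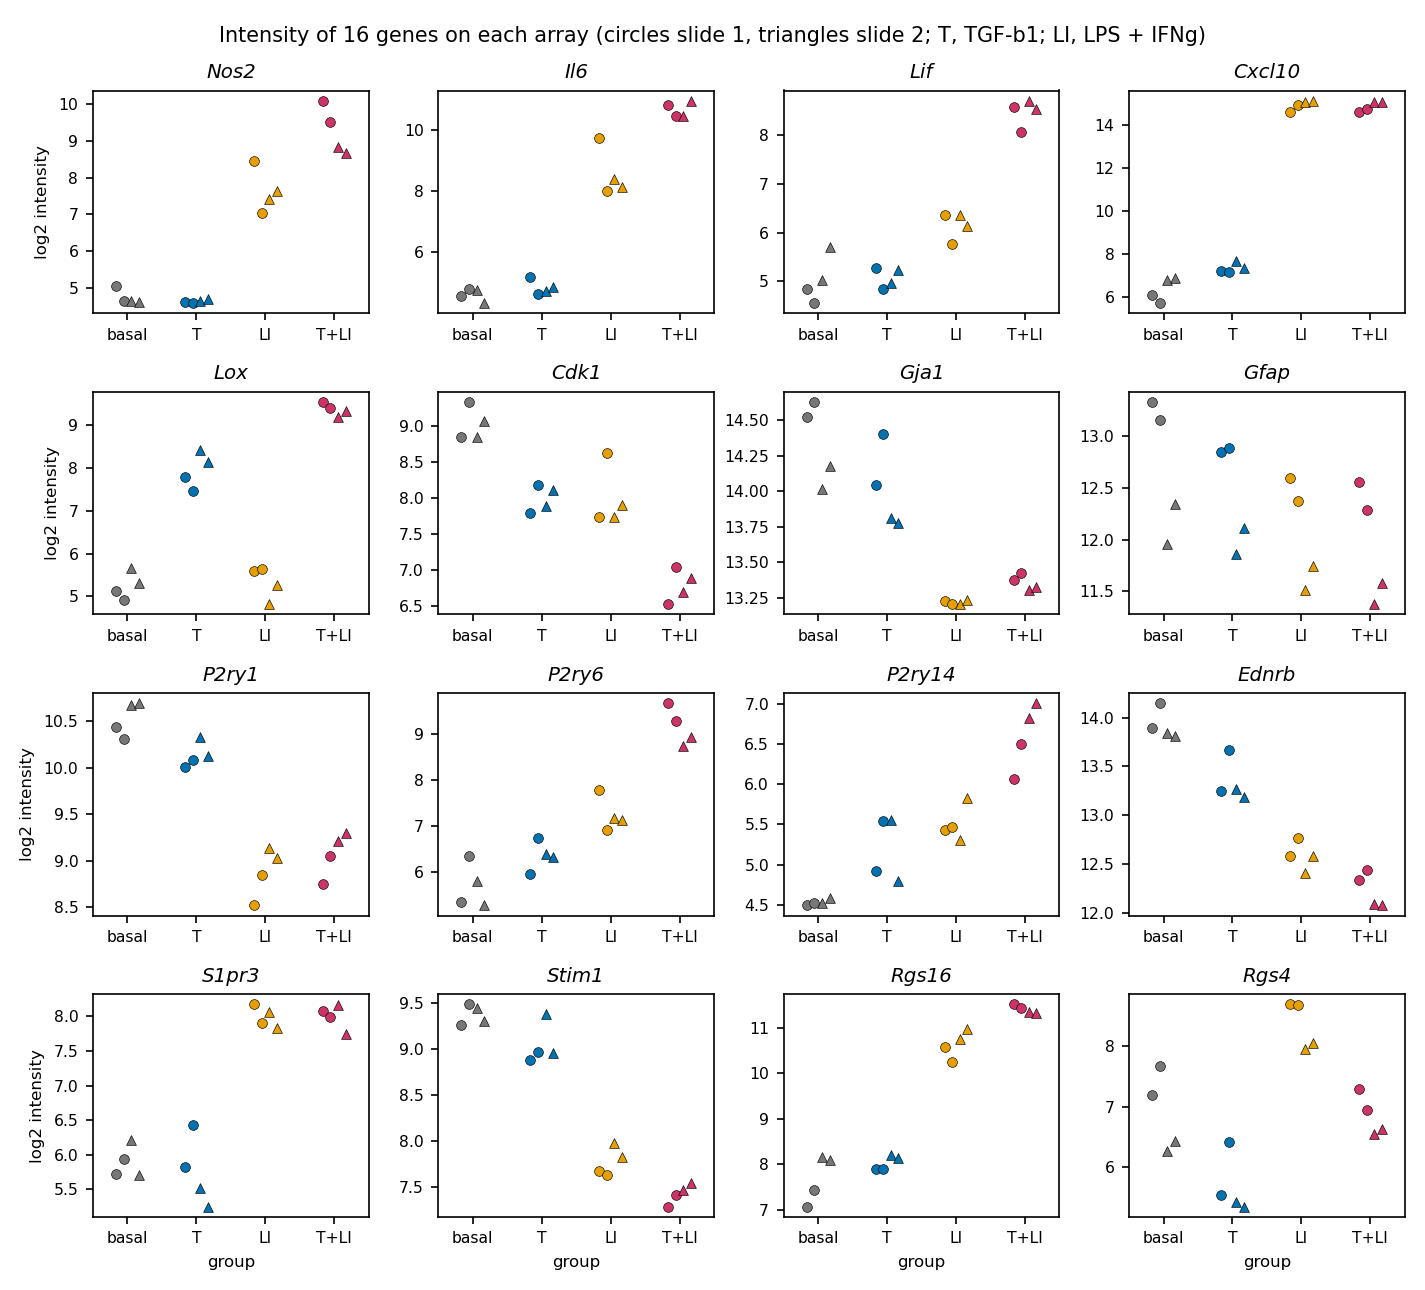
Normalized log2 intensity of 16 genes on each of the 16 arrays (circles, slide 1; triangles, slide 2). Nos2 and Il6 are highest in the cultures with TGF-β1 and LPS plus IFNγ, P2ry1 and Ednrb are lower with LPS plus IFNγ than in basal cultures, and Rgs4 is lower with TGF-β1 both with and without LPS plus IFNγ, and higher with LPS plus IFNγ both with and without TGF-β1.

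TGF-β1 moved many of the same genes with and without LPS plus IFNγ, and a small set differently. Across 8843 genes its log2 fold changes in the 2 settings, which share no array, correlated with a Pearson r of 0.67 and a Spearman rho of 0.56, and 69.8% had the same sign (r of 0.64 and 0.55 within the slides). Of the genes past the threshold, 278 were higher in both (31.9 by chance) and 190 lower in both, and 1 and 2 went opposite ways. Mfap4 and Pmepa1 rose and Id1 and Cdk1 fell in both. The effect of LPS plus IFNγ without and with TGF-β1 correlated with an r of 0.95. The interaction asks, gene by gene, whether the effect of TGF-β1 differs in the presence of LPS plus IFNγ.

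**Figure D4:**
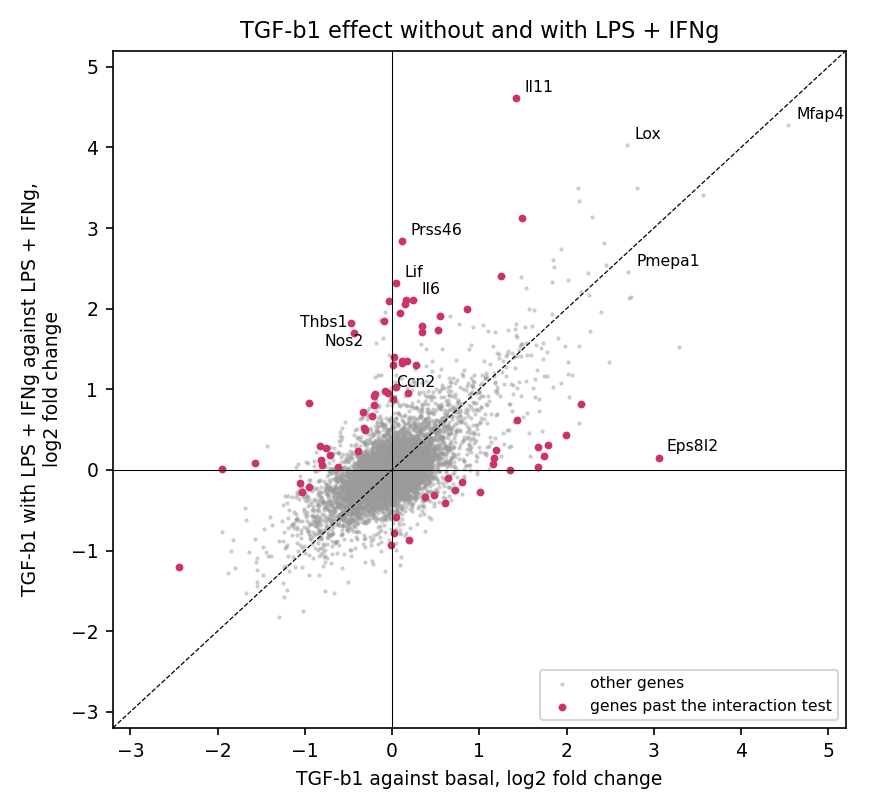
Each point is 1 of 8843 genes, by its log2 fold change with TGF-β1 alone (horizontal) and with TGF-β1 before LPS plus IFNγ (vertical); the dashed line marks equal effects. The 73 genes past the interaction test are red, and Il11, Prss46 and Lif lie above the line and Eps8l2 below it.

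By limma 73 genes passed the interaction, 50 with a more positive and 23 with a more negative effect of TGF-β1 when LPS plus IFNγ followed. With the replicate block 237 passed, including all 73, and with the slide block 203; with only 2 arrays per group, 7 passed within slide 1 and 4 within slide 2, where 740 and 1021 had an unadjusted p under the same limit. Leaving out replicate 2 or 3 of the group with TGF-β1 and LPS plus IFNγ left 48 and 45. The effect on Il11 was 3.19 ± 0.28 larger on the log2 scale (adjusted p = 2.2e-05; above background on 0 of 4 basal arrays), on the protease gene Prss46 2.72 ± 0.16 (above background only on the 4 arrays with TGF-β1 and LPS plus IFNγ), on the GTPase gene Rab15 2.29 ± 0.37 (3 of 4 LPS plus IFNγ arrays above background), on Lif 2.28 ± 0.31 (1 of 4 basal and 2 of 4 TGF-β1 arrays) and on the matrix gene Thbs1 2.13 ± 0.38. It was also larger on Mcm6 (1.23 ± 0.17, 1 of its 3 probes not past), Ass1 (1.02 ± 0.18) and Ccn2 (1.00 ± 0.12). Ccn2 lies near the top of the scale without LPS plus IFNγ, so an effect of TGF-β1 there may not show. The most negative were Eps8l2 (-2.90 ± 0.32; above background on 1 of 4 basal arrays, all TGF-β1 arrays and no array with LPS plus IFNγ, so its effect there is a difference at background), Pdlim3 (-1.64 ± 0.27, 1 of 4 basal arrays and 1 of 4 with both treatments above background), Cps1 (-1.57 ± 0.23, above background on TGF-β1 arrays alone, 1 of its 2 probes not past) and Litaf (-1.48 ± 0.19, over 13 on the log2 scale in all groups but basal), with the cross-linking gene Loxl1 at -1.35 ± 0.24.

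For Il6 the interaction was 1.87 ± 0.40 (adjusted p = 0.0422). It lay above background on 0 of 4 basal and 1 of 4 TGF-β1 arrays, so the effect without LPS plus IFNγ is a difference at background, as it is for Nos2 (1 of 4 and 0 of 4). Leaving out any array except LPS plus IFNγ replicate 1 ended the Il6 call, at an adjusted p of 0.0513 to 0.098, as did median scaling (0.0742) and no detection filter (0.0651). Nos2 did not pass (1.74 ± 0.41, adjusted p = 0.0608), but did with the replicate block (adjusted p = 0.0115), with an offset of 50 (0.0443), with array weights (0.0457), without LPS plus IFNγ replicate 1 (0.0156) and without replicate 4 of the group with both treatments (0.0397). Among receptors P2ry6 (1.25 ± 0.37, adjusted p = 0.173) passed only without background subtraction (0.00997) or with an offset of 50 (0.0177). P2ry1 (0.58 ± 0.21) passed only with a block (adjusted p = 0.0323 with the replicate number). Cxcl10 (-1.02 ± 0.32, adjusted p = 0.218) likewise passed with the block (0.0196). It lies near the top of the scale with LPS plus IFNγ, which can itself give a negative value. Rgs4 did not pass (-0.28 ± 0.44). Of 5 lists past camera's interaction test, cytokines and chemokines (median 0.40, 0.21 and 0.51 within the slides; adjusted p = 0.00412) and interferon-response genes (0.15, 0.04 and 0.15 within the slides, 0.02 without background subtraction; 0.00892) lay higher, and cholesterol synthesis (-0.34; 0.000566), stress genes (-0.13, or -0.08 without background subtraction; 0.00412) and NF-κB signalling (-0.18, -0.09 and -0.20 within the slides; 0.0294, and 0.0513 with the slide block) lower. All 5 were lost with an estimated correlation, at an adjusted p of 0.401 for the first 4 and 0.422 for NF-κB signalling. The replicate block added fibroblast and meningeal markers (0.019, and 0.0456 with the slide block; fry 0.0246) and astrocyte markers (0.0473). With an estimated correlation these had an adjusted p of 0.401 and 0.645.

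With both treatments the cultures stood farthest from basal. Sertm1 fell the most (-4.60 ± 0.19), and Nos2 was 4.53 ± 0.29 higher and Il6 at least 47.1-fold higher (4 arrays per group; Nos2 above background on 1 of 4 basal arrays). This comparison asks for the joint state: 1978 genes were higher and 3037 lower, 1894 by at least 1 on the log2 scale, with a median of -0.12 over all genes (5781 passed with the replicate block). Cxcl9 rose at least 749-fold and Ccl2 at least 332-fold, and Cxcl1 (9.72 ± 0.37, 1 of 4 basal arrays), Ccl7 (9.39 ± 0.26, 1 of 4) and Ccl5 (9.18 ± 0.18, 3 of 4) were next. The cilia-related genes Ccno (-4.19 ± 0.68) and Akap14 (-3.62 ± 0.53, 3 of 4 arrays with both treatments) and Aif1l (-3.91 ± 0.40) fell, as did Ppp1r1b (-3.93 ± 0.44, or -1.55 as the mean of its detected probes, 2 of its 3 probes not past). Cytokines had 27 of 27 higher, interferon response 40 of 41, matrix 18 of 32 higher and 4 lower (median 0.62, 0.93 and 0.39 within the slides, 0.39 without background subtraction; adjusted p = 0.00115, and adjusted p = 0.172 with an estimated correlation), cholesterol 16 of 20 (0.86; adjusted p = 1.3e-05, and adjusted p = 0.258 with an estimated correlation) and cell cycle 3 higher and 19 lower of 27 (-1.19, or -0.66 without background subtraction; adjusted p = 0.00158, and adjusted p = 0.355 with an estimated correlation). Ependymal markers had a median of -0.85 in these arrays, with 5 of 8 lower and 1 higher (camera adjusted p = 0.451, fry 0.00416). Lox (4.10 ± 0.22, 3 of 4 basal arrays), Tnc (2.12 ± 0.13), Timp1 (4.83 ± 0.15), Cyp51 (2.12 ± 0.25) and Lss (2.04 ± 0.22) rose, and Cdk1 (-2.23 ± 0.19) and Mcm4 (-1.91 ± 0.14) fell.

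Astrocyte markers had 17 of 31 lower and 2 higher against basal (median -0.75, or -0.67 at the bounds, adjusted p = 0.0049, and adjusted p = 0.478 with an estimated correlation), with Sox9, a transcription factor of the astrocyte lineage, at -1.75 ± 0.20, Slc39a12 at -1.63 ± 0.13, Gja1 at -0.98 ± 0.15 and Gjb2 at 4.56 ± 0.42 (2 of 4 basal arrays). Markers of the oligodendrocyte lineage (-0.66), neurons (-0.47), endothelium (-0.30) and fibroblasts (-0.31) also had negative medians. Among receptors Ednrb (-1.69 ± 0.13) and P2ry1 (-1.45 ± 0.15) were lower and S1pr3 (2.10 ± 0.20) and P2ry14 (at least 2.83-fold) higher, and Rgs4 did not pass (-0.04 ± 0.31). Microglia markers had 0 of 7 past the limma test beside these (0 before adjustment, median 0.18, -0.14 and 1.18 within the slides, 0.04 without background subtraction, camera adjusted p = 0.716, fry 0.739). On each slide alone, 1 of them passed on slide 1 and 5 on slide 2.

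Set against TGF-β1 alone, which asks for the effect of LPS plus IFNγ on cultures that had already met TGF-β1, 1570 genes were higher and 2664 lower, 1363 by at least 1 on the log2 scale (median of all genes -0.14; 5156 passed with the replicate block). Cxcl9 (9.89 ± 0.16, 1 of 4 TGF-β1 arrays above background), Ccl7 (9.37 ± 0.26, 1 of 4), Cxcl1 (9.31 ± 0.37, 2 of 4), Ccl5 (9.03 ± 0.18, 3 of 4) and Ccl2 (at least 323-fold) led the rises, and Nos2 rose by at least 4.13 on the log2 scale and Il6 by 5.81 ± 0.29 (1 of 4). Fam107a (-3.52 ± 0.26), the calcium sensor gene Ncald (-3.52 ± 0.16), Ppp1r1b (-3.17 ± 0.44, or -1.31 as the mean of its detected probes, 2 of its 3 probes not past), Vstm4 (-3.02 ± 0.26, and -1.13 by its other probe) and Eps8l2 (at least 6.97-fold lower) fell. The 27 cytokines and chemokines all rose (median 3.87, or 2.53 without background subtraction; adjusted p = 1.2e-25), as did 40 of 41 interferon-response genes (4.29, or 3.97 at the bounds) and 25 of 26 of antigen presentation (4.40, or 4.27). Ednrb (-1.11 ± 0.13) and P2ry1 (-1.06 ± 0.15) fell, and S1pr3 (2.24 ± 0.20), P2ry14 (1.40 ± 0.21, 2 of 4 TGF-β1 arrays) and Rgs4 (1.17 ± 0.31) rose.

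Without background subtraction 77 of the 258 called gene values given here moved by over 1.5 times, and with a larger offset 40 did. Of these 0 reversed, but candidates whose call was lost had mostly been left out, so this is partly built in. With 4 arrays per group a gene that did not pass is not shown to be unchanged.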

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

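All tests of explanations in this part were chosen only after the results were seen; the comparisons themselves were fixed before.

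The effect of TGF-β1 differed with LPS plus IFNγ, by the interaction test, for 14 of the named genes. It was larger on the log2 scale for Il11 (3.19), Prss46 (2.72), Rab15 (2.29), Lif (2.28), Thbs1 (2.13), Il6 (1.87), Mcm6 (1.23), Ass1 (1.02) and Ccn2 (1.00), and lower for Eps8l2 (-2.90), Pdlim3 (-1.64), Cps1 (-1.57), Litaf (-1.48) and Loxl1 (-1.35). For Il11, Prss46, Lif, Il6, Eps8l2, Pdlim3 and Cps1 at least 1 group lies at background on most arrays, so the size of the interaction is uncertain, as it is for Ccn2 and Litaf near the top of the scale. The Il6 call was lost without any single array except LPS plus IFNγ replicate 1 and with median scaling (adjusted p = 0.0742). Of 100 groupings of the residuals, only 1, the real grouping, gave as many as 73 genes, and the highest of the others gave 0. Regrouping these arrays thus did not yield the gene count. The residuals still hold the interaction, which widens the spread of such genes. As the replicates may also be technical, chance is not excluded. For the 5 lists, 9 of 100 groupings gave as many, up to 8.

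Astrocyte markers were lower with LPS plus IFNγ, 18 of 31. A lower share of astrocytes would raise the markers of other cell types, and of 47 such markers 19 fell and 6 rose, against 60.9% of falls among all genes past the threshold (exact binomial test p = 0.152). Against the other genes their log2 fold change was -0.33 over genes (rank-sum 95% interval -0.54 to -0.11) but -0.25 over arrays (-0.61 to 0.11), which includes 0. The interval over arrays leaves the difference between slides in its spread. Within the slides the medians of these lists were negative on both, except for microglia (-0.69 and 0.69). No interval was computed within slides, so a lower share of astrocytes and lower expression in them cannot be told apart. With median scaling 16 markers stayed lower past the threshold, which argues against the quantile step as the cause. Both scalings give the arrays a common centre, so an error there would not show. Every group has 2 arrays on each slide, so a difference between slides cannot by itself part the groups.

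Inflammatory genes rose with LPS plus IFNγ, among them all 27 measured cytokines and chemokines. Background subtraction does not account for this, since 27 rose without it. Microglia left in the cultures could contribute, and their markers differed between arrays: the mean log2 intensity of Cd52, Fcer1g, Laptm5 and Lyz2, the markers above background on all 8 arrays with LPS plus IFNγ, ran from 5.98 to 8.90 over the arrays with LPS plus IFNγ alone and from 6.53 to 8.92 over those with both treatments. Ccl3, Ccl4, Il1b and Tnf were chosen after their values were seen, because their slopes over the former arrays reached the lowest slope of a marker. Following the markers there is thus no result. Over the latter arrays their median slope was 1.34 (lowest slope of a marker 0.69). Each marker is part of the mean it is set against, so the marker slopes average 1 by construction. Within slides their median slope was 1.08 (lowest marker 0.87). But the replicates fall in the same order of marker intensity in both groups, slide 1 above slide 2, so for these 4 genes microglia and a difference between replicates cannot be told apart. The other 17 cytokines below a log2 intensity of 13 had a median slope of 0.0244 over the arrays with both treatments (-0.27 to 0.08 without single arrays) and an upper quartile of 0.24. Within slides their median slope was 0.28, their upper quartile 0.62 and their highest slope 0.79 (lowest marker 0.87). They are the genes left once those with high slopes were taken out, and the order of replicates is the same for them. The slopes thus show only that these genes followed the markers less steeply than the markers themselves, some of them in part within slides. They do not decide whether microglia were a source. The 6 brighter ones lie near the ceiling and stay open, as does a response of the astrocytes themselves.

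TGF-β1 alone changed 1119 genes, and the slides differed, but each group has 2 arrays on each slide. Of these genes 920 stayed past the threshold in the same direction with median scaling, which argues against the quantile step as the whole cause. An error shared by both scalings, such as in the common centre of the arrays, would not show. Using only the 8 arrays of the comparison, the real split gave 889 genes and a split of the same arrays by slide 943. With the slide as a block 1983 genes passed, and 541 and 726 within the slides. A direct effect of the cytokine stays open as a hypothesis.

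The arrays of a pairwise comparison allow only 8 splits that part all 4 replicate pairs, too few for a share under 0.05. The real gene counts were 889 (TGF-β1 against basal), 4362 (LPS plus IFNγ against basal), 4899 (both treatments against basal), 676 (both against LPS plus IFNγ) and 4141 (both against TGF-β1), each reached by 1 split, the real one, with 0 as the highest other. The other splits keep the treatment effect in the data, where it widens the spread of the changed genes. A count of 0 was thus largely built in and does not speak against chance. The split by slide gave 628 genes in the comparison of both treatments with LPS plus IFNγ, where the slide block gave 1474. The lists called were 8, 10, 11, 7 and 7 in that order, with 6, 10, 12, 8 and 8 as the highest other and 1, 2, 3, 2 and 4 splits with as many. Uneven splits carry part of the real effect into the list tests, so these counts do not decide about chance either.

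Single arrays lay far from the other 3 of their group in 8 of 212 groups tested; chance marks about 1 in 20, or 10.6. In LPS plus IFNγ replicate 1 the mean log2 intensity was 11.54 for the interferon list (others 11.34 to 11.35) and 10.21 for the NF-κB list (others 9.86 to 9.90). For proteases and inhibitors basal replicate 4 lay at 8.21 (others 8.01 to 8.03) and TGF-β1 replicate 4 at 8.44 (others 8.34 to 8.35). For endothelial markers replicate 2 with both treatments lay at 7.44 (others 7.11 to 7.14). Nos2 was 5.06 in basal replicate 1 (others 4.62 to 4.65), F2r 12.72 in LPS plus IFNγ replicate 2 (others 13.05 to 13.10) and Ednrb 13.67 in TGF-β1 replicate 2 (others 13.19 to 13.26).

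Among 1719 probes with no listed gene, which enter no comparison, 721 lay above background. Of these 90 passed with TGF-β1 against basal, 333 with LPS plus IFNγ against basal, 384 with both treatments against basal, 59 with both against LPS plus IFNγ, 305 with both against TGF-β1 and 4 in the interaction. A stand-in probe for the vomeronasal receptor gene Vmn1r65, chosen after its values were seen, had a mean intensity of 460.9 with LPS plus IFNγ and 458.2 with both treatments, against 117.9 in basal and 127 in TGF-β1 cultures. It is 1 of 19 stand-in probes above background.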

How the results depend on the processing

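The alternatives were chosen before the data were seen, except camera with an estimated correlation and the slide block. Candidate genes whose call was lost had mostly been left out of the text, so the named values are those that held: of 4689 results of 283 values under other settings 4553 kept their side of the threshold and 0 reversed, and without single arrays 4508 of 4528 did. Not all of these results are separate tests. Each probe on its own kept the chosen probe of a gene (283 of 283 the same), and the series matrix values repeat those without background subtraction. Some of the arrays left out lie outside the compared groups. The number of arrays and, for dim genes, the signal over background limit the values: without background subtraction 77 called values moved by over 1.5 times, with an offset of 50 40, as the mean of the probes 4 and with median scaling 1. Counts are given as TGF-β1 against basal, both treatments against LPS plus IFNγ, and interaction (1119, 860 and 73). The replicate block gave 2086, 1594 and 237 and the slide block 1983, 1474 and 203, since the slide left the spread; apart from those given in the report, the replicate block changed no call of a named gene. Fewer arrays left 541, 505 and 7 within slide 1 and 726, 609 and 4 within slide 2. An adjusted p under 0.01 gave 533, 456 and 26, and a log2 fold change of at least 1 gave 247, 231 and 48 (1583 for LPS plus IFNγ and 1894 for both against basal, 1363 for both against TGF-β1). Stricter detection left 45 interaction genes. Leaving out an array gave 783 to 1154, 679 to 858 and 45 to 71; replicates 2 and 3 with both treatments gave 48 and 45, and the cause was not tested. The lists gave 47 calls, 50 with the replicate block (46 of the 47 kept), 47 with the slide block (45 kept), 21 with an estimated correlation, 18 with the slide block added, and 87 by fry, which tests each list without the other genes and turned the nitric oxide list in LPS plus IFNγ against basal (adjusted p = 0.000553; others 0.849 to 0.991). The correlation of 0.67 was 0.76 over genes past the threshold in either and 0.55 within slide 2; the cause was not tested.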

Other observations

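The tests in this part rest on comparisons fixed before the data were seen, and their grouping here was chosen only after the results were seen.

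When TGF-β1 came before LPS plus IFNγ, Il11 was 4.61 ± 0.20, Lif 2.32 ± 0.22 and Il6 2.10 ± 0.29 higher on the log2 scale than with LPS plus IFNγ alone, as was the chemokine gene Ccl8 (0.85 ± 0.15). The interaction was 3.19 ± 0.28 for Il11 and 2.28 ± 0.31 for Lif. Both genes lay at background on most basal arrays, so these sizes are uncertain. The interaction call of Il6 was lost in most fits that left out a single array. The arginine-recycling gene Ass1, lower with LPS plus IFNγ (-1.52 ± 0.13), was higher when TGF-β1 came first (0.81 ± 0.13), as was Nos2 (1.64 ± 0.29).

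Rgs4, a brake on Gq signalling, rose with LPS plus IFNγ without TGF-β1 (1.45 ± 0.31) and after it (1.17 ± 0.31), and was lower with TGF-β1 before LPS plus IFNγ than with LPS plus IFNγ alone (-1.49 ± 0.31). With TGF-β1 alone it fell (-1.21 ± 0.31, adjusted p = 0.0168), a call lost with only the compared groups in the fit (adjusted p = 0.0507) and without basal replicate 1 (0.0527) or 2 (0.059) or TGF-β1 replicate 4 (0.0552). With both it did not differ past the threshold from basal (-0.04 ± 0.31). Its interaction did not pass (-0.28 ± 0.44).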
